A study of Mus musculus with 12 samples.

How the data were processed

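Reduced representation bisulfite sequencing was made from mouse DNA. The method cuts genomic DNA with MspI, an enzyme that cuts at CCGG, so that CpG-rich stretches are over-represented, and bisulfite turns unmethylated cytosine into a base read as T. The 12 libraries comprised 4 whole embryos and 4 whole placentas of strain C57BL/6 at embryonic day 10.5. They also comprised the trophoblast stem (TS) lines TSRS and TSG28, each with 1 undifferentiated library (day 0) and 1 differentiated library (day 4). These lines are of other strains than the tissues. TS cells are the cultured stem cells of the trophoblast, the lineage that builds most of the placenta. Per the labels' protocols, the TS lines were grown with bFGF, heparin and medium conditioned by embryonic fibroblasts, and were differentiated by taking these away and adding retinoic acid. Groups, replicate numbers, lines and days came from the sample labels. Nothing in the labels says which placenta belongs to which embryo, nor whether the replicates came from separate litters, so p-values measure the spread between these samples.

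The submitters' processing notes name Trim Galore 0.3.3, BSMAP 2.74, Picard and the mouse build mm10; the settings and the role of each tool are not given in the sources used here. The authors deposited 1 table per library with 1 row per cytosine of a CpG and strand. Per the file headers, each row holds the coverage, a count of reads, and the shares of those reads with C (methylated) and T, in percent. Between 0.0795% and 0.220% of a library's rows gave a methylated count that was not whole to within 0.0005 of the coverage, so a small part of the deposited percent values was not made from the coverage beside it. Coverage stopped at 65535 in 4 libraries. Some rows were listed with 0 reads and were left out.

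Methylated counts were the coverage multiplied by the share of C. Both strands of a CpG were summed, and a CpG was used where every library of the comparison had at least 10 reads. Chromosomes X and Y were left out of the main comparisons. The depth, summed over cytosines, ran from 59910669 reads in TSRS at day 4 to 101296386 reads in TSRS at day 0, and between 61.9% and 68.6% of a library's CpGs had at least 10 reads. Reads carry no molecular identifiers here, so binomial intervals and tests on reads cover counting error only. Mitochondrial CpGs, taken as unmethylated, read as methylated in 0.0140% to 0.153% of reads.

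The gene table used gives the symbol, type, start and end of each RefSeq gene on GRCm38.p6, whose chromosomes are those of mm10, but neither strand nor exons, and no genome sequence was used. The planned promoter window therefore could not be placed at the gene start. In its place, each of 34614 protein-coding and lncRNA genes was given the end with more CpGs seen in any library, from 1000 bp outside to 500 bp inside the gene. An end shared to within 10 bp by at least 3 genes was passed over. This is called the gene end below. Against strands written from general knowledge for 57 genes, the 5′ end was the end chosen in 48, and among the 36 Hox genes of that check in 28. For the same reason, exon, intron, island and repeat classes were replaced by gene ends, the rest of genes, the space outside genes, and 3 classes of CpGs per 100 bp. These last classes count the CpGs seen in any library, not those of the genome sequence.

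Tiles of 100 bp with at least 2 CpGs, and gene ends with at least 5 CpGs, were tested with a logistic model of methylated and unmethylated counts, with a Pearson dispersion per feature of at least 1 and an F test (quasi-binomial test below). P-values were adjusted by Benjamini and Hochberg. A tile was called at an adjusted p under 0.01 and a difference of at least 20 percentage points, a gene end at an adjusted p under 0.01 and at least 10 points. The embryo and placenta fit used those 8 libraries (6 residual degrees of freedom). The day 4 term of the TS lines was fitted over all 12 libraries, with a level for the embryo, the placenta and each line (7 residual degrees of freedom), so the spread of the TS libraries was taken to be like that of the tissues. Same-numbered TS libraries are the same line, so the line served as the pairing. Library means, features and imprinted regions were compared by exact two-sided permutation tests over all 70 arrangements of 4 and 4, of which the smallest possible p is 0.0286. Lists were compared with all other tested gene ends by Fisher's exact test, two-sided, adjusted over 15 lists and both directions at 0.05. Neighbouring genes of a cluster, as in the Hox and protocadherin lists, are not independent, so Fisher's p-values can be too small there. Imprinted regions were windows placed from general knowledge of 18 germline regions, described by the first and last CpG used.

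Tests, thresholds, 15 gene lists with 563 entries (560 matched, some through synonyms) and the rule for named genes were fixed before the data were examined. The rule took the 10 largest called differences in each direction among protein-coding gene ends whose libraries did not overlap. It took up to 4 called members of each list by size of the difference, or up to 2 tested members of a list with none. It also took all tested genes of the methylation machinery, all imprinted regions with data, the 3 largest called tiles in each direction in or within 5000 bp of a gene, and for the TS lines the 5 largest gene ends and 3 largest tiles in each direction. The TS test called nothing, so TS genes were taken by size without a call. Alternatives were coverage minimums of 5 and 20, an upper coverage limit at the 99.9th percentile, the sex chromosomes, each library left out, the replicate number as a block, a dispersion fixed at 1, limma 3.58.1 on log2 ratios with 1 read added to each count, other thresholds, window sizes and tile sizes, and the added ones named in the closing section.

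The tests were checked on simulated counts drawn with the real coverage of each feature. Unchanged features had the same level in all libraries, and the same spread between libraries was assumed for every feature. The shares recovered need not hold for the real data. With 200 of 182597 tiles changed, the quasi-binomial test recovered 13 of 100 tiles changed by 30 points and 18 of 100 changed by 45 points between placenta and embryo, and limma recovered 47 and 73. With 25000 tiles changed by 30 points and 25000 by 45 points, the quasi-binomial test recovered 87.9% and 99.3%, and no unchanged tile was called. Among 14152 gene ends it recovered 79 of 100 changed by 20 points and 98 of 100 changed by 40 points. For day 4 against day 0 over 149999 tiles it recovered 27 and 34 of 100 with 200 tiles changed, and 59.2% of those changed by 30 points and 84.2% of those changed by 45 points with 10000 changed by each amount, where 2 unchanged tiles were called. Among 13423 gene ends for the same contrast it recovered 77 of 100 and 84 of 100 at 20 and 40 points. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9 and R 4.3.3.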

Results

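DNA methylation was measured at single CpGs in 4 whole mouse embryos and 4 whole placentas at midgestation, and in the trophoblast stem lines TSRS and TSG28 before (day 0) and after 4 days of differentiation. Reads summed over cytosines came to 60150656, 84028510, 91263040 and 75163346 in embryos 1 to 4, and to 66899795, 79133526, 81184917 and 72762949 in placentas 1 to 4. The TSRS libraries held 101296386 reads at day 0 and 59910669 at day 4, and the TSG28 libraries 89128292 and 69437532. The comparisons ask where the placenta and the embryo of the same age differ in methylation, and whether TS cells change when they differentiate. Levels of embryo and placenta are means ± SD over 4 libraries per tissue; each TS line had 1 library per day and no replicate. Positions are on mm10.

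The placenta was less methylated than the embryo. Over 935463 autosomal CpGs the mean level was 30.9% ± 0.265 in the embryo and 18.9% ± 0.503 in the placenta, a difference of -12.0 percentage points (exact permutation test, two-sided, p = 0.0286, the smallest possible with n = 4 per tissue). The difference per CpG was largest outside genes, where the embryo had 66.0% ± 0.636 and the placenta 35.3% ± 1.49. Inside genes the levels were 39.7% ± 0.309 and 25.7% ± 0.519, and at gene ends 4.00% ± 0.0415 and 2.97% ± 0.0824. Each of the 19 autosomes was lower in the placenta, from -14.4 points on chromosome 1 to -8.92 points on chromosome 19, each with an exact p of 0.0286. The size of the mean difference depends on the weighting: as a read-weighted mean it was -3.95 points, and with methylation odds corrected by the level of imprinted regions -6.96 points (exact p = 0.0286 for both). With at least 20 reads per CpG the difference at gene ends was -0.534 points.

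The number of CpGs seen per 100 bp went with the size of the difference. A CpG-rich stretch that was only partly read can fall into a lower class. Where 1 to 4 CpGs were seen in 100 bp, the embryo had 59.8% ± 0.568 and the placenta 34.1% ± 0.853. At 5 to 9 CpGs the levels were 24.9% ± 0.155 and 17.5% ± 0.506. At 10 or more CpGs the placenta was the higher tissue, by 0.131 points, at 1.43% ± 0.0148 in the embryo and 1.57% ± 0.0751 in the placenta. All 6 of these feature comparisons had an exact adjusted p of 0.0286. The difference of the densest class no longer passed without any single embryo (0.118 to 0.132 points, adjusted p 0.0571 to 0.0857 by the exact test).

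**Figure D1:**
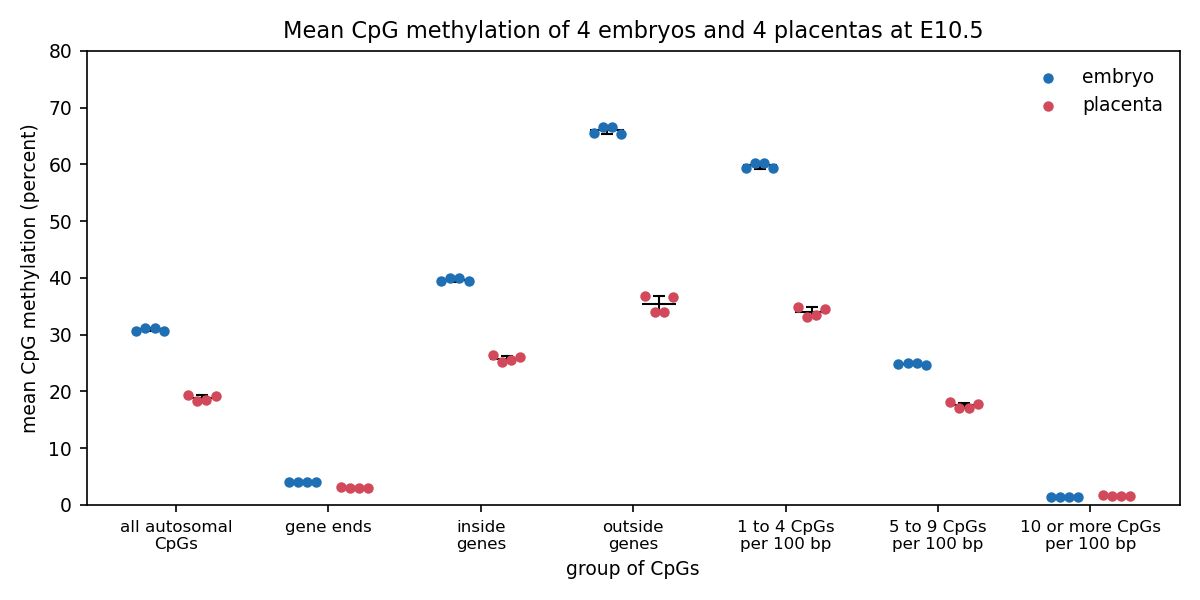
Mean CpG methylation in percent (vertical axis) for all autosomal CpGs and 6 groups of them (horizontal axis). Points are libraries, horizontal bars the mean of 4 and error bars the SD; outside genes the 4 embryos lie between 65.4% and 66.5% and the 4 placentas between 34.0% and 36.7%.

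At the scale of 100-bp tiles, 59379 of 182597 tested tiles differed between the tissues. Of these, 57183 were lower in the placenta, falling from a mean of 83.5% ± 0.673 in the embryo to 41.7% ± 1.5, and 2196 were higher, rising from 6.96% ± 0.206 to 35.9% ± 2.0. Over all tested tiles, called or not, 93.1% of the 59729 tiles over 80% in the embryo lay between 20% and 80% in the placenta, 1.67% lay under 20% and 5.25% stayed over 80%. The share of tiles over 80% was 31.6% ± 0.980 in the embryo and 2.76% ± 0.763 in the placenta, and the share between 20% and 80% was 18.6% ± 0.946 and 44.1% ± 0.799 (exact p = 0.0286 for each, n = 4). The share under 20% was 49.8% ± 0.0337 and 53.1% ± 0.0388; with class limits of 10% and 90% the lowest class was instead 1.67 points smaller in the placenta (a difference of -1.67). With at least 20 reads per CpG 34304 tiles were called, and without placentas 1 and 4, whose means lie nearest to the embryo, 33837.

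**Figure D2:**
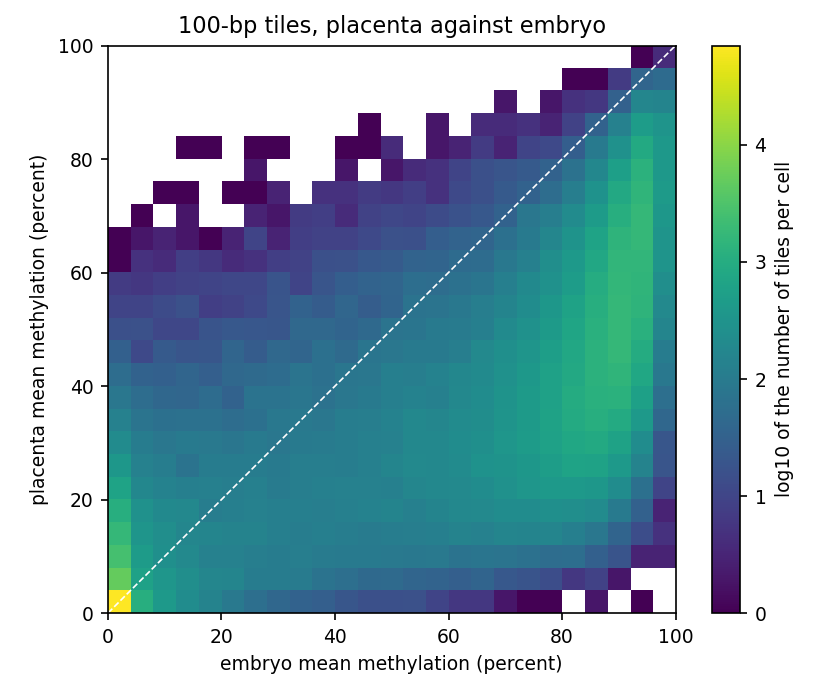
Mean methylation of 182597 tiles in the embryo (horizontal axis, percent) against the placenta (vertical axis, percent); the color gives the log10 of the number of tiles in each cell and the dashed line equal levels. Most tiles over 80% in the embryo lie below the line, between 20% and 80% in the placenta.

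The largest single-tile gains lay inside Arhgap23, a Rho GTPase activating protein, on chromosome 11 from 97501101 to 97501200 (13.7% ± 1.68 in the embryo, 84.0% ± 4.99 in the placenta) and in the tile before it from 97501001 to 97501100 (9.33% ± 3.82 and 72.8% ± 10.7). The next lay inside Zfpm1, a cofactor of GATA transcription factors, on chromosome 8 from 122337001 to 122337100 (16.7% ± 2.44 and 80% ± 2.84). The largest losses lay inside Rusc2 on chromosome 4 from 43399801 to 43399900 (94.0% ± 6.44 and 3.89% ± 3.40), 3471 bp from Defa38, a defensin gene, on chromosome 8 from 21091401 to 21091500 (96.1% ± 4.53 and 11% ± 7.56), and inside Gm16976 on chromosome 14 from 44865801 to 44865900 (96.2% ± 4.17 and 11.4% ± 4.83). Reads per library ran from 20 to 1100 at these 6 tiles.

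Gene ends changed in both directions. Of 14152 tested, 965 were lower and 257 higher in the placenta; among 11456 protein-coding genes 509 were lower and 168 higher, and among 2696 lncRNA genes 456 and 89. With the odds correction 925 were lower and 743 higher, and of the tiles 35393 were lower and 6876 higher. The largest gain was at Urm1, a ubiquitin-like modifier of transfer RNA thiolation, where the end on chromosome 2 from 29844496 to 29845996 rose from 1.73% ± 0.722 to 56.7% ± 2.15 over 24 CpGs (quasi-binomial adjusted p = 9.55e-05). Exoc6, a part of the exocyst, rose from 2.99% ± 1.60 to 42.5% ± 6.45, and Oxct2b, a ketone body enzyme of the testis, from 6.68% ± 1.75 to 41.8% ± 4.69. Tdgf1, a Nodal coreceptor, rose from 2.33% ± 1.33 to 32.8% ± 9.68, and Dbx2, a homeobox gene, from 0.449% ± 0.0706 to 30.6% ± 6.06. The others among the 10 largest gains were 4930404N11Rik, 4933428G20Rik (whose window holds the gained tiles of Arhgap23), Dpep1, Ercc6l2 and Hoxa3.

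The largest loss was at Traf3ip3, an adaptor of lymphocytes, which fell from 89.8% ± 5.88 to 16.8% ± 3.36 at its end on chromosome 1 from 193174504 to 193176004 over 6 CpGs (quasi-binomial adjusted p = 0.000353). Klrb1f, a receptor of natural killer cells, fell from 94.0% ± 3.51 to 23.1% ± 11.4, Tlr12, a Toll-like receptor, from 82.8% ± 3.82 to 13.7% ± 4.86, and Itgax, an integrin of dendritic cells, from 81.1% ± 2.08 to 18.7% ± 4.12. Spaca4, an acrosome protein of sperm, fell from 91.1% ± 4.23 to 20.6% ± 3.69, and Capns1, the small subunit of calpain, from 77.3% ± 4.65 to 10.6% ± 4.82. A window shared by Rad51c and Tex14 fell from 95.2% ± 2.17 to 31.0% ± 7.0, and a window shared by Dnajc5g and Slc30a3 from 89.8% ± 4.49 to 26.7% ± 4.04. At the other end of each gene 567 ends were called in place of 1222, with 470 lower and 97 higher; there Dpep1 fell by 26.7 points and 4933428G20Rik by 23.8 points, and Urm1 differed by -0.114 points.

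Most tested genes that are normally active in germ cells were lower in the placenta. Of 25 tested germline genes, 19 were lower in the placenta and 0 higher (20 lower when adjusted over the list alone), against 6.70% of the other gene ends (Fisher's exact test, adjusted p = 2.1e-16). The mean of the list was 67.0% ± 1.05 in the embryo and 35.2% ± 2.33 in the placenta. Slc25a31, an ATP carrier of sperm, fell from 85.4% ± 4.35 to 27.4% ± 6.38, Sycp1 of the synaptonemal complex from 84.9% ± 2.19 to 28.2% ± 3.87, Hormad1, a regulator of meiotic recombination, from 87.6% ± 2.77 to 32.9% ± 6.05, and Asz1, of the piRNA pathway, from 91.5% ± 3.75 to 37.1% ± 7.41. Dazl and Ddx4, markers of germ cells, fell from 82.8% and 65.8% to 45% and 26.4%. Matched on the embryo level of gene ends, a test added after the data had been seen, the germline excess did not pass (adjusted p = 0.618 by the Cochran-Mantel-Haenszel test), nor did it across the other ends of the genes.

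Among Hox genes, which pattern the body axis, more ends than elsewhere were higher in the placenta. Neighbours within a Hox cluster are not independent, so Fisher's p-value for them can be too small. Of 31 tested Hox genes, 8 were higher in the placenta and 0 lower (8 higher when adjusted over the list alone; Fisher's exact test, adjusted p = 8.75e-07), and the list mean was 0.875% ± 0.0705 in the embryo and 9.33% ± 0.705 in the placenta. Hoxa3 rose from 0.705% ± 0.614 to 31.7% ± 11.4, Hoxa7 from 5.79% ± 1.88 to 29.0% ± 4.34, Hoxb1 from 1.89% ± 0.642 to 24.4% ± 6.25 and Hoxd12 from 1.28% ± 0.427 to 22.0% ± 2.14. By the known strand of these genes, the end used for Hoxa3, Hoxa6, Hoxb6 and Hoxc6 was the 3′ end, and across the other ends the list showed no excess. Hoxa3, Hoxa6 and Hoxb6 are among the called ends, so these gains do not lie at the gene start. Hoxa3 did not pass when embryo 2, 3 or 4 was left out (29.7 to 34.2 points over the 8 fits).

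Of 86 other developmental transcription factors, 11 were higher and 1 lower (11 and 2 when adjusted over the list alone; Fisher's exact test for higher, adjusted p = 4.2e-06), with list means of 1.32% ± 0.109 and 5.30% ± 0.501. Tbx4 and Pitx1, regulators of hindlimb growth, rose from 2.98% ± 0.472 to 30.4% ± 2.09 and from 0.463% ± 0.139 to 18.7% ± 1.64. Six3, of the forebrain and eye, rose from 0.203% ± 0.260 to 19% ± 5.64, and Pax9 from 0.0965% ± 0.193 to 17.1% ± 8.30; the Pax9 call ended without any 1 embryo and without placenta 2 or 4 (12.9 to 18.6 points over the 8 fits). Called at 20 points, the list no longer stood apart (adjusted p = 0.860 by Fisher's exact test). Genes of the Fgf, Wnt, Bmp and Hedgehog pathways and their regulators did not pass the threshold in any of 40 cases, although the list mean was 0.769% ± 0.0568 in the embryo and 3.08% ± 0.469 in the placenta; Shh stood at 0.179% ± 0.255 and 8.45% ± 3.68, and Wnt5a at 6.59% ± 2.23 and 14.6% ± 2.34.

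Genes of pluripotent and early embryonic cells moved both ways. Of 16 tested, 3 were higher and 2 lower (4 and 2 when adjusted over the list alone; Fisher's exact test for higher, adjusted p = 0.0167, 0.113 without embryo 3 and 0.724 without placentas 1 and 4). Prdm14, a regulator of primordial germ cells, rose from 0.591% ± 0.653 to 25.9% ± 2.02 together with Tdgf1 (not called without embryo 3), whereas Zfp42 (Rex1) fell from 79.2% ± 3.92 to 22.2% ± 7.10 and Gdf3 from 69.9% ± 3.40 to 20.3% ± 5.91. The clustered protocadherins, cell surface proteins of neurons, had 6 of 20 members lower and 0 higher (8 lower when adjusted over the list alone; Fisher's exact test, adjusted p = 0.0125). Neighbours in these clusters are not independent either, so that p-value can be too small. Pcdha12 fell from 38.4% ± 2.46 to 9.24% ± 1.68 and Pcdha5 from 38.4% ± 3.82 to 11.4% ± 2.70. The protocadherin excess did not hold without embryo 1, 2 or 3 or placenta 2 or 3 (adjusted p up to 0.151 by Fisher's exact test) nor stratified by CpG count or by embryo level (adjusted p = 0.0630 and 0.0999 by the Cochran-Mantel-Haenszel test), and at the other, shared ends of these genes the direction was the opposite, with Pcdhgb1 34.9 points higher.

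Among markers of cell types, 3 of 7 blood genes were lower (4 when adjusted over the list alone; Fisher's exact test, adjusted p = 0.0449): Hba-x, an embryonic globin, fell from 71.3% ± 3.44 to 28.3% ± 6.96, Klf1 of red cells from 91.4% ± 2.06 to 58.8% ± 8.53 and Vav1 of blood cells from 47.1% ± 4.31 to 22.6% ± 4.44. The blood excess did not hold without embryo 1, 3 or 4 (adjusted p up to 0.261 by Fisher's exact test) nor stratified by CpG count or by embryo level (adjusted p = 0.0954 and 0.917 by the Cochran-Mantel-Haenszel test). The Vav1 call ended without the same embryos (-26.5 to -23.1 points over the 8 fits), and Hba-x was measured at its 3′ end. For Klf1 the end of higher coordinate was used as well. The gene table gives no strand, so that end need not be the gene start. Of 14 neural and muscle genes 4 were lower (4 when adjusted over the list alone; Fisher's exact test, adjusted p = 0.0531; without 1 library 0.0296 to 0.547, under 0.05 only without placenta 4), among them Ckm, the muscle creatine kinase, from 75.2% ± 2.26 to 28.9% ± 6.81, and Myog from 86.2% ± 2.54 to 54.1% ± 5.18. Of 21 trophoblast genes 1 changed (1 when adjusted over the list alone): Krt7, a keratin of trophoblast, fell from 33.0% ± 2.76 to 4.37% ± 0.677. Of 7 endothelial genes 1 changed (1 when adjusted over the list alone): Cldn5, a claudin of tight junctions, rose from 2.21% ± 0.866 to 17% ± 1.42. None of 11 genes of the maternal decidua passed (0 when adjusted over the list alone), at list means of 4.05% ± 0.276 and 5.30% ± 0.320. Neither did any of 13 housekeeping genes, at 0.0465% ± 0.0219 and 0.0856% ± 0.0818.

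None of 8 tested genes of the DNA methylation machinery passed (0 when adjusted over the list alone). Dnmt3b, Mbd2, Tdg, Tet1, Tet2, Tet3 and Uhrf1 had means under 0.3% in both tissues, with the highest value, 0.279% ± 0.129, at Tet1 in the placenta. Uhrf2 stood at 0.551% ± 0.155 and 1.02% ± 0.468.

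**Figure D3:**
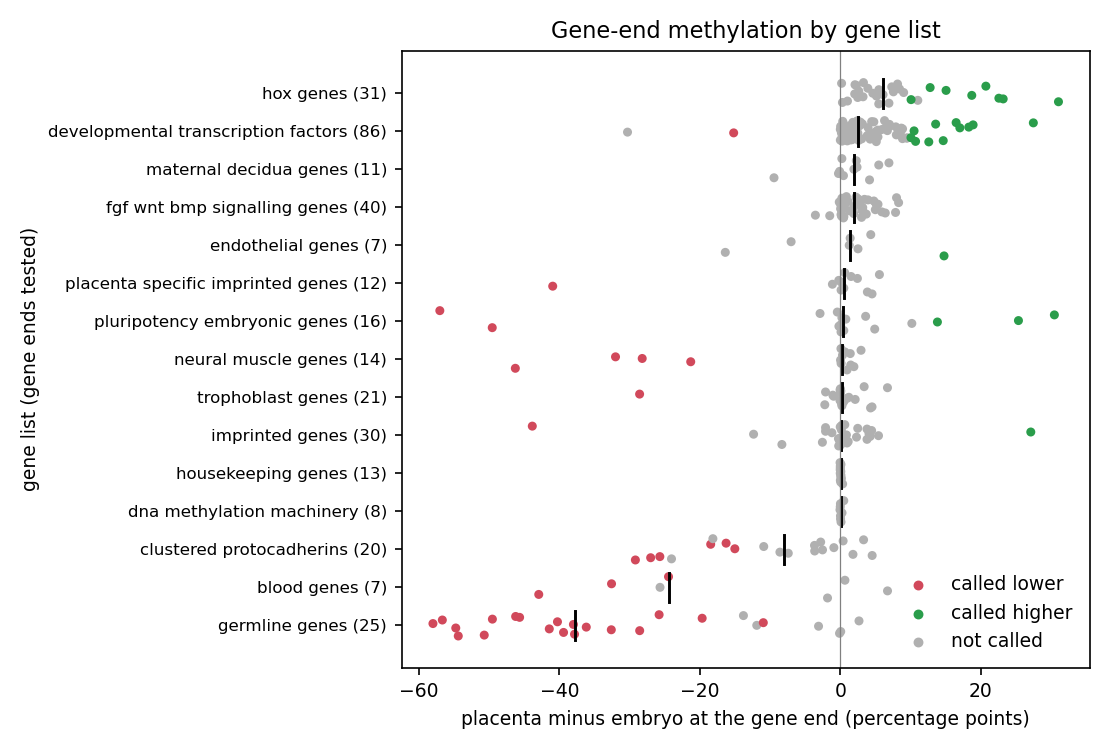
Difference between placenta and embryo at the gene end, in percentage points (horizontal axis), for each tested member of 15 lists (vertical axis, number tested in brackets). Each point is a gene end, colored by its call, and the black bar is the list median, which is -37.8 for germline genes and 6.06 for Hox genes.

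Germline imprinted regions, which carry methylation on the allele of one parent, were compared as regions. Of 18 regions 14 had at least 5 usable CpGs, and 0 passed after adjustment by the exact permutation test, whose smallest p of 0.0286 lets a few regions among 14 never reach 0.05. The window placed for the imprinting control region of H19 and Igf2, methylated on the paternal allele, had 63.9% ± 4.75 in the embryo and 36.2% ± 5.59 in the placenta. It held 6 CpGs on chromosome 7 between 142575795 and 142581386. This window also overlaps the H19 gene, so some of its CpGs may lie outside the control region. Weighted by reads, its difference was -18.3 points. The maternally methylated region at Nnat had 19.3% ± 1.81 and 34.0% ± 2.29 over 46 CpGs on chromosome 2 between 157560098 and 157561742 (exact p = 0.0286 for both regions, adjusted 0.20). By the quasi-binomial test of read counts, a test added after the data had been seen, 1 region passed at 0.05: Nnat (adjusted p = 0.00117), with 0.0531 for H19 and Igf2. At the other 12 maternally methylated regions the means ranged from 18.6% at Kcnq1ot1 to 30.5% at Peg13 in the embryo, and from 15.2% at Kcnq1ot1 to 33.8% at Peg13 in the placenta. The regions at Snrpn, Peg10, Nap1l5, Mcts2, Plagl1, Grb10, Zrsr1, Igf2r, Impact and Gnas lay between those limits.

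Among 30 tested genes of the list of imprinted genes, Zdbf2 was lower in the placenta, at 85.5% ± 6.33 and 41.6% ± 8.40, and Nnat higher, at 15% ± 3.06 and 42.0% ± 5.19 (1 lower and 1 higher when adjusted over the list alone). Of 12 genes imprinted in the placenta, Jade1 was lower, at 95.4% ± 2.17 and 54.4% ± 15.1 (1 lower when adjusted over the list alone). The Zdbf2 call ended without embryo 1, 2 or 4 or placenta 1 or 2 (-47.2 to -40.3 points over the 8 fits), and the Jade1 call without any 1 library but placenta 4 (-46.0 to -35.7 points).

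**Figure D4:**
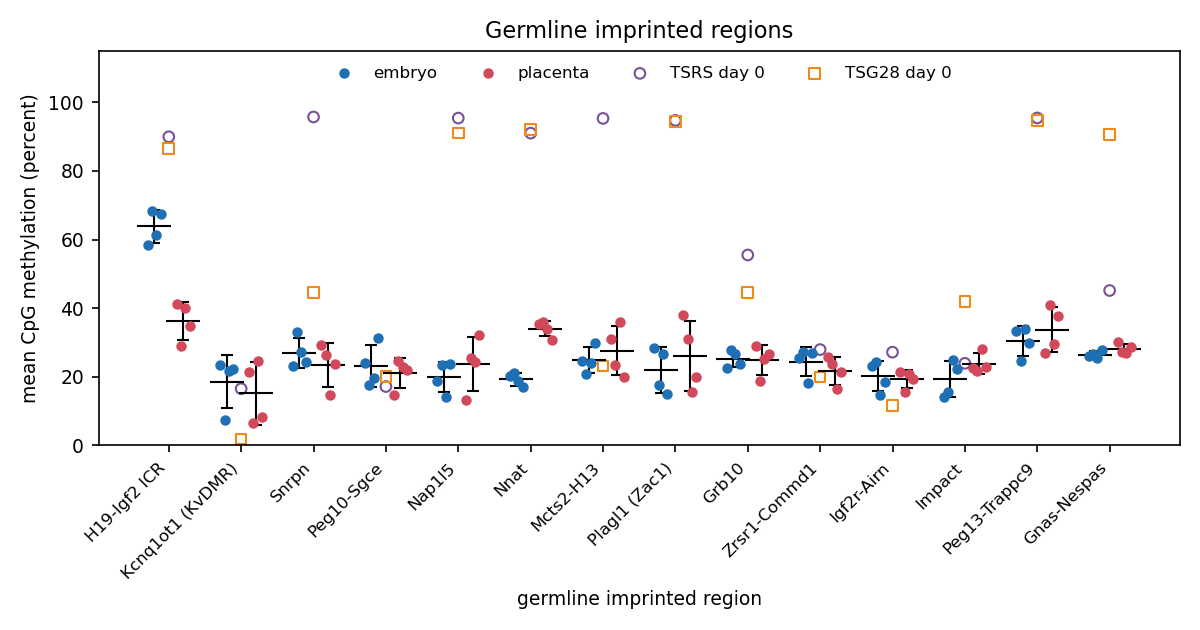
Mean CpG methylation in percent (vertical axis) at 14 germline imprinted regions (horizontal axis). Filled points are embryo and placenta libraries with their mean and SD, and open symbols the TS lines at day 0; at Nap1l5 the lines lie at 95.4% and 91.0%.

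Differentiation of the TS lines was accompanied by lower levels in both. Over 792469 CpGs TSRS had 33.2% at day 0 and 27.1% at day 4, a difference of -6.07 points, and TSG28 had 35.1% and 30.8%, a difference of -4.31 points. The differences were larger outside genes (-14.3 points in TSRS and -9.49 in TSG28) than inside genes (-7.86 and -5.68) or at gene ends (-1.19 and -0.976). With 1 library per line and day, the line means were not tested.

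In the 12-library quasi-binomial fit 0 of 149999 tiles passed for day 4 against day 0. The smallest adjusted p was 0.0615, 32530 tiles had an unadjusted p under 0.05 (29673 lower and 2857 higher at day 4), and limma called 28. By size alone, 17384 tiles changed by at least 20 points on average and the same way in both lines, of which 17096 were lower. With the dispersion fixed at 1, that is with counting error only, 17141 tiles were called. The difference between the lines in their change was tested as an interaction, and 0 tiles passed (9254 at an unadjusted p under 0.05).

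At gene ends 0 of 13423 passed, 2357 had an unadjusted p under 0.05 (2039 lower), limma called 0, and 35 passed at an adjusted p under 0.05, all lower. The genes that follow were taken by size and were not called. Gulo, an enzyme of vitamin C synthesis, went from 92.2% (95% Wilson interval 88.5 to 94.7) to 32.4% (25.8 to 39.7) in TSRS and from 83.3% (75.2 to 89.2) to 39.3% (29.5 to 50.0) in TSG28. Adm2, a peptide hormone, went from 90.1% (86.4 to 92.9) to 55.6% (47.1 to 63.7) and from 91.4% (84.5 to 95.4) to 46.7% (38 to 55.6). The other large decreases were at Trim16, Kifc3 and Pdgfrb; at Pdgfrb, a growth factor receptor, TSRS went from 86.4% to 21.6% and TSG28 from 46.9% to 36.4%. The largest increases were at Pramel1 (39.4% to 51.0% in TSRS, 40.3% to 60% in TSG28), the window shared by Ntn5 and Sec1 (60.1% to 82.1%, 52.4% to 59.8%), 4931417E11Rik and Serpine1, the plasminogen activator inhibitor (60.2% to 77.8%, 63.7% to 72.7%). Reads per library and gene end ran from 83 to 1079 at these genes.

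Among members of the lists, named after their values were seen, Sox17, an endoderm factor, stood at 87.2% (84.0 to 89.8) and 68.3% (62.9 to 73.2) in TSRS and at 93.9% (91.7 to 95.6) and 77.6% (74.1 to 80.8) in TSG28. Lefty1, an inhibitor of Nodal, stood at 87.1% and 68.3% in TSRS and at 83.3% and 56.4% in TSG28. The tiles with the largest increases lay inside Cldn12, G2e3 and Ctif, and those with the largest decreases inside Anxa11 and Bmp8a and 3538 bp from Prdm13, where TSRS went from 60% to 0% and TSG28 from 85.0% to 3.57%.

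The TS lines were set beside the tiles called between placenta and embryo. At 43188 tiles lower in the placenta, where the embryo had 83.2% and the placenta 41.9% ± 1.51, TSRS stood at 80.1% at day 0 and 63.5% at day 4, and TSG28 at 78.8% and 67.9%. At 1668 tiles higher in the placenta, where the embryo had 7.29% and the placenta 36.2% ± 2.04, TSRS stood at 80.7% and 73.0% and TSG28 at 82.1% and 75.1%. At the 105143 tiles not called, where the embryo had 17.4% and the placenta 14.4% ± 0.323, the values were 28.2% and 23.9% in TSRS and 30.8% and 27.4% in TSG28. The day 0 lines thus lay near the embryo at the placenta-lower tiles and above both tissues at the placenta-higher tiles. They lay above both tissues at the tiles not called as well, by less. The lines differ from the tissues in strain and by culture, so this comparison cannot tell those apart from a difference of cell type.

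**Figure D5:**
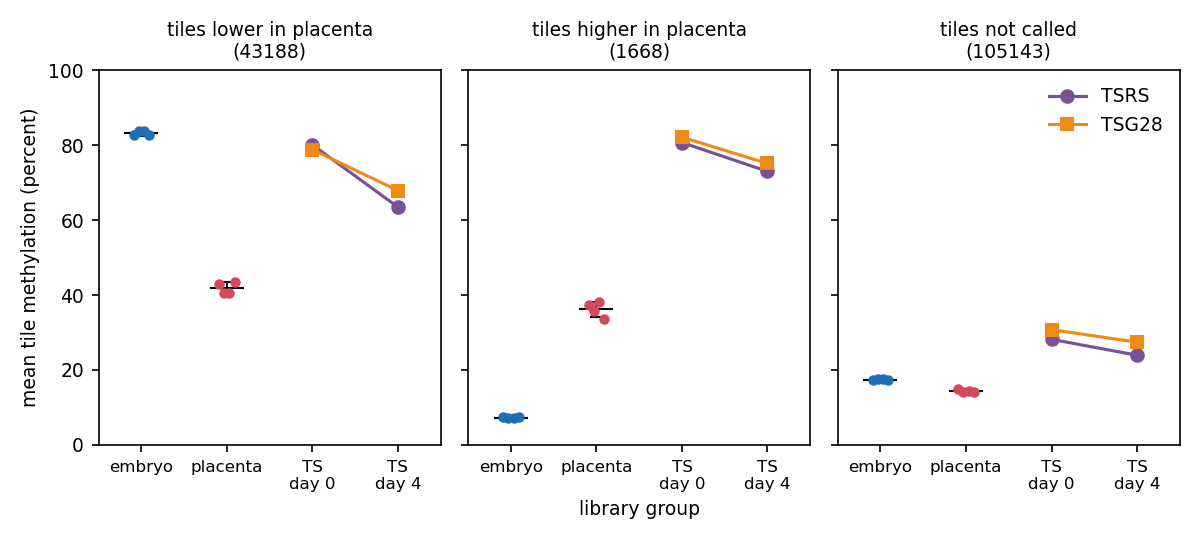
Mean tile methylation in percent (vertical axis) in embryo, placenta and TS libraries (horizontal axis) at 3 sets of tiles, with the number of tiles in the titles. Points are libraries, bars the mean and SD of 4, and lines join day 0 to day 4 of a TS line; at placenta-lower tiles the lines end at 63.5% and 67.9%.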

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

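The tests of mitochondrial methylation, of the imprinted regions of the placenta and of the TS lines, and of the paternally methylated region were chosen after the values had been seen; the splits of the libraries, the tests of TS tiles by their level in the placenta and of single CpGs in imprinted windows were set out beforehand.

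Of 216 groups of 4 reported values, 19 held a library far from the other 3, where chance alone gives about 5% of groups, or 10.8. In 5 of the 19 the other values were all 0 and 1 window was counted for a pair of genes, which leaves 13, close to chance. Placenta 1 stood apart in 6 of them: the mean of the maternal decidua genes was 5.78% against 5.08% to 5.19% in the other placentas, that of the housekeeping genes 0.208% against 0.0398% to 0.0515%, and the Polr2a end 0.430%, the Urm1 end 53.5%, the Hoxd12 end 25.1% and the Pcdhgb1 end 2.13%. Embryo 2 stood low at the Kcnq1ot1 region (7.29% against 21.7% to 23.3%) and at Ckm (71.8%), and was the only embryo above 0 at B2m (0.0739%) and Polr2a (0.0641%). Embryo 3 stood low at the Zrsr1 region (18.1%) and at the window of Rad51c and Tex14 (92.0% in both). Placenta 3 stood high at Pax9 (29.5% against 12.4% to 13.7%) and Mbd2 (0.187%) and at 0 in Tet3, placenta 2 was the only placenta above 0 at Tet2 (0.173%), placenta 4 stood high at Pcdha5 (15.4%), and embryo 4 was the only embryo above 0 at Pax9 (0.386%).

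Cytosines listed with no reads, which no comparison uses, were more numerous in the TS libraries than in the tissues. On the autosomes, X and Y there were 3574 in TSRS at day 0, 3485 in TSRS at day 4, 3999 in TSG28 at day 0 and 3886 in TSG28 at day 4, against 624 to 999 in the 8 tissue libraries. The libraries of TSRS shared 57.7% of them and those of TSG28 59.6%, as a percent of the smaller list, against 40.4% to 41.6% between the lines and 22.3% to 36.9% between libraries of the same tissue.

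Lower methylation in the placenta was the largest pattern. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many tiles (the real one, 59379, highest other 0) and 1 as many gene ends (the real one, 1222, highest other 0). That is the smallest share the splits allow. A split that mixes the tissues puts their difference into the spread, so its low count was fixed in advance. The splits therefore cannot exclude chance. Incomplete conversion in the embryo is argued against by mitochondrial CpGs, which read as methylated in at most 0.153% of reads in an embryo library. A loss of methylated reads across the whole genome of the placenta libraries was modelled by the odds change at the placenta-lower tiles. It would have taken the maternally methylated imprinted regions from 23.7% in the embryo to 4.2%. Their median in the placenta was 24.7% (SD 1.71 over 4 libraries). Those tiles were chosen for a large loss, so a milder even loss would predict a smaller fall. The window of the paternally methylated region, which also overlaps the H19 gene, fell from 63.9% to 36.2%. A loss limited to other parts of the genome is not covered. A difference between the tissues, or in their cell types, stays open as a hypothesis and was not tested further.

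Lower methylation at day 4 in both TS lines was weighed next. Incomplete conversion at day 0 is argued against by mitochondrial methylation of at most 0.0694%. Among tiles over 70% in both lines at day 0, those over 70% in embryo and placenta lost 45.9% of what placenta-lower tiles lost in TSRS and 58.4% in TSG28 (mean 52.1%). They began higher (93.2% and 91.3% against 87.7% and 86.5%), so an even loss of odds predicts shares of 64.8% and 71.0%, and the bounds of 50% and 80% set beforehand were wrong and decide nothing. At 13 maternally methylated regions the day 4 level exceeded that prediction by a median of 14 points in TSRS (SD over regions 8.86) but of 8.36 points in TSG28 (SD 9.54), within the spread, and lay above it in 13 and 9 regions. The prediction rests on tiles chosen for levels over 70% at day 0, whereas the regions were not chosen that way. Such a choice can enlarge the fall of the tiles by day 4 and set the prediction for the regions too low. The excess over it therefore decides nothing in TSRS or in TSG28. An even loss stays open in both lines, as the whole cause or as a part of the decrease. A change with differentiation stays open too.

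Maternally methylated imprinted regions stood at a median of 23.1% in the embryo, under the 50% that 1 methylated allele of a pair would give. Windows reaching beyond the region are argued against: 82.6% of 448 CpGs lay between 10% and 35%, and 8.93% lay under 10%. Methylated copies under-represented in all libraries may account for it and would lower every level in the report. The paternally methylated region at 63.9% is a single window of 6 CpGs that also overlaps the H19 gene, and it cannot decide this. Such a bias therefore cannot be told apart from a property of the regions. No biological explanation was tested.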

How the results depend on the processing

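The other gene end, shared ends, lists, features and classes without 1 library, the fits without placentas 1 and 4, the odds correction, the quasi-binomial test of imprinted regions, the lists stratified by embryo level and limma for the TS lines were added after the data had been seen; the other alternatives were planned. The mean difference between placenta and embryo kept its sign in all alternatives run, but was -3.95 points as a read-weighted mean. Coverage limits the count of tiles: at least 20 reads per CpG gave 34304 tiles (32631 lower) and 766 gene ends (546 lower), because fewer features are tested. Without placentas 1 and 4 the mean difference was -12.4 (exact p 0.0667, the smallest possible with 4 against 2), with 33837 tiles (32116 lower) and 748 gene ends (530 lower). With methylation odds raised 3.33 times, the factor that takes the median imprinted region to 50%, the mean difference was -6.96 points, with 35393 lower and 6876 higher tiles and 743 higher gene ends; the call held, and the split moved toward gains. At 10 and 5 points 5684 tiles and 553 gene ends were higher, and at 30 and 15 points 775 and 131. Single CpGs gave 121641 calls (114769 lower, 6872 higher), and 500-bp tiles 1191 higher. At least 3 CpGs gave 1879 gene ends (1596 lower), and the other gene end 567 (470 lower, 97 higher) and 0 lists with an excess of lower ends. Stratified by CpG count, only germline genes had such an excess, and protocadherins and blood genes lost it. Stratified by embryo level, which compares members with other ends of like level in the embryo, 0 lists had it. Without 1 library, and not stratified, the number ran from 1 to 4, lowest without embryo 1 or embryo 3. The quasi-binomial test passed 1 imprinted region in place of 0. With limits of 10% and 90% the lowest class reversed, at -1.67 points. The densest feature was 0.0969 to 0.153 points higher without 1 library, weaker without each embryo.

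The labels do not say that replicate numbers pair the tissues. Deviations of same-numbered libraries correlated at -0.00846 to -0.00155, and 0 of 8 libraries correlated best with its own number, whereas the shares of X reads were alike (2.06%, 1.25%, 2.06% and 1.25% in embryos 1 to 4, 2.41%, 1.34%, 2.43% and 1.53% in placentas 1 to 4), so whether they pair stays open. With the replicate block, which leaves 3 residual degrees of freedom, 0 tiles (0 lower, 0 higher) and 0 gene ends (0 lower, 0 higher) were called, and the mean difference of -12.0 had an exact p of 0.125, the smallest the pairing allows. In the TS fit, no replicate block (no pairing by line) also gave 0 tiles and 0 gene ends, so it changed no call.

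For the TS lines the mean change was -5.91 points at 5 reads (-6.97 in TSRS, -4.85 in TSG28) and -3.78 at 20 reads (-4.38 and -3.18); with 1 line it ran from -6.38 to -4.49. A dispersion fixed at 1 gave 17141 tiles (16866 lower, 275 higher) and 1008 gene ends (976 lower, 32 higher), limma 28 tiles (27 lower, 1 higher), and an adjusted p under 0.05 gave 35 gene ends (35 lower). The cause was not tested in any of these except as stated. The directions that reversed at named genes were all at other or shared gene ends: Urm1 (-0.114), Dpep1 (-26.7), 4933428G20Rik (-23.8), Pcdhgb1 (34.9 in both settings), and the log2 odds ratio of lower protocadherins (-4.57). Of 50 named and called gene ends, 41 kept the call without any 1 of the 8 libraries. The 9 that did not were Gfap, Hoxa3, Jade1, Myh6, Pax9, Pcdhgb1, Tdgf1, Vav1 and Zdbf2.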

Other observations

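Families of genes were compared by the letters that begin their symbols, a test chosen after the data had been seen. Of 200 families with at least 8 tested ends, 3 passed Fisher's exact test after adjustment over 400 tests. Members of a family can be neighbours in a cluster and are then not independent, so these p-values can be too small. Keratins had 15 of 24 ends lower in the placenta (adjusted p = 1.01e-12), with means of 58.5% in the embryo and 35.1% in the placenta. Krt5 and Krt17 fell from 76.0% ± 4.04 to 35.1% ± 6.66 and from 81.2% ± 3.93 to 40.4% ± 7.97, and Krt7 was among the 15 as well. Olfactory receptors had 10 of 14 ends lower (adjusted p = 3.54e-09), with means of 61.8% and 31.8%, and Olfr551 fell from 81.6% ± 6.31 to 20.7% ± 3.55. Matched on the embryo level, neither excess passed (adjusted p = 0.926 for both by the Cochran-Mantel-Haenszel test). The Hoxa cluster was the only family past the threshold of Fisher's test in the other direction, with 3 of 9 ends higher (adjusted p = 0.0356). These were Hoxa3, Hoxa6 and Hoxa7. Hoxa3 and Hoxa6 were measured at the 3′ end, and the Hoxa3 call ended without embryo 2, 3 or 4. Matched on embryo level, excesses of higher ends passed for Hoxa, Prdm, Hspb, Hoxb, Hoxd, Tbx and Nkx, on 2 or 3 called ends each. Their adjusted p ran from 4.71e-12 to 0.00307 by the Cochran-Mantel-Haenszel test. That test is an approximation for large counts, so with so few called ends these p-values can be far too small. The odds ratio of Hoxa was 35.6 without matching and 34.7 with it, and among these families only that of Hspb rose. By Fisher's exact test, which was not matched, only Hoxa of these families passed.

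Several imprinted regions of the TS lines stood far above both tissues, with 1 library per line and day and no test. Strain and culture differ between the lines and the tissues here too. At Nap1l5, Nnat, Plagl1 and Peg13 TSRS had 95.4%, 91.0%, 94.7% and 95.4% at day 0, and TSG28 had 91.0%, 92.0%, 94.4% and 94.7%. At Snrpn and Mcts2 TSRS had 95.7% and 95.3%, whereas TSG28 had 44.5% and 23.1%. At Gnas TSG28 had 90.7% and TSRS 45.1%. At Kcnq1ot1, Peg10 and Zrsr1 both lines lay under 30% at day 0, with 1.90% at Kcnq1ot1 in TSG28 at day 0 and 16.8% at day 4. The Hox list had 34.0% in TSRS and 26.3% in TSG28 at day 0, over 27 ends, where placentas 1 to 4 had 8.69%, 6.94%, 7.74% and 8.23%, and the Fgf, Wnt, Bmp and Hedgehog genes 13.9% and 22.7%.

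Placenta libraries correlated less with each other across CpGs than embryo libraries, at 0.902 to 0.935 against 0.976 to 0.981. Levels between 20% and 80%, where counting error is larger, were more frequent in the placenta (44.1% of tiles against 18.6%). The lower correlations may come from this and need not mean that the placentas differ more from each other, which was not tested. Placenta 4 lay toward the embryo at placenta-lower tiles by 6.37% of the gap and at placenta-higher tiles by 13.5%, whereas placenta 1 lay toward it by 4.35% at the former and away from it at the latter (-2.43%).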
